A study of Homo sapiens with 45 samples.

How the data were processed

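Gene expression was measured in peripheral blood mononuclear cells, the lymphocytes and monocytes that a Ficoll gradient separates from blood, with 45 Agilent 2-colour arrays. Per the labels, RNA was extracted on columns and linearly amplified. The Cy5 channel held the sample of a patient or healthy person and the Cy3 channel a reference called a negative control, whose RNA the labels do not describe. No array had the dyes exchanged.

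Per the file headers, Agilent Feature Extraction software made 1 scanner file for each array, in versions A.7.5.1, 9.5.1.1, 9.5.3.1 and 10.2.1.3. Per the file headers, these files hold raw spot and local background intensity as pixel medians in each channel. They also hold, per the file headers, a log10 ratio of Cy5 over Cy3 that the software had corrected for background and dye. The value table deposited by the authors holds natural log (ln) ratios of Cy5 over Cy3 for 45 arrays. Its columns were compared with the scanner files: 43 matched their own file best and 2 matched another file better. No value here decides whether the columns or the scanner files were exchanged. The scanner files were used as labelled, and the value table served as an alternative; both arrays belong to the paired comparison.

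The arrays came in 2 designs sharing 41000 probes, from 24 slides scanned on 10 days, named A to J here. Of these probes, 23434 were named through an accession, 2317 through a current symbol and 1043 through an older symbol of the RefSeq gene table, and 14206 kept the name in the files. The files used give no genome build, so no coordinates are reported. XIST, TSIX and Y-linked probes (104) were removed before any test.

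Median signals were background corrected with the normexp method (offset 50) and loess normalized within each array in limma 3.58.1 under R 4.3.3. Spots that the scanner software called non-uniform were set to missing and control spots were given no weight. The spots of a probe were averaged. A probe was kept when it was well above background in Cy5 on at least 5 of the 45 arrays, which left 34504 probes. The probe of highest mean intensity stood for its gene, giving 26189 genes or transcripts.

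The groups followed the labels: 16 operational tolerance, 10 chronic rejection, 5 healthy control, 7 pre-transplant and 7 post-transplant arrays. The 5 comparisons between independent groups came from 1 limma fit of 38 arrays in 4 groups. The post-transplant and pre-transplant arrays were compared in a separate limma fit of 14 arrays with the patient as a block, since the series text pairs them by patient number. P values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Errors of log2 changes are standard errors of the fit. Replicate numbers follow the labels, which number patients in the paired groups and samples in tolerance and chronic rejection.

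Lists of marker genes of blood cell types, of response genes and of published tolerance genes, 23 in all, were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 23 lists, and again with an estimated correlation. The published tolerance genes came from blood studies of tolerant kidney recipients, so they are not independent of this field's patient groups. Some lists share genes, so their results are not fully separate. The calcineurin and NFAT list shares TNF with the NF-kB list, and EGR2, EGR3 and NR4A1 with the immediate early list. The published panel of 10 genes shares CD79B, TCL1A, MS4A1, FCRL1, FCRL2 and PNOC with the B cell list and SH2D1B with the cytotoxic list. A signature score was the mean of the genes higher in operational tolerance than in chronic rejection minus the mean of those lower. With fewer than 10 genes past the threshold in a direction, the 50 of smallest p were taken, a rule fixed before the data were examined. Paired scores were compared with an exact two-sided sign-flip test over 128 sign patterns.

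The comparisons, tests, lists and most alternatives were fixed before the data were examined, as was the rule for the genes named. It takes, among genes past the threshold that kept their direction with each array left out, the 8 of largest change in each direction. From each list past its test, and from the B cell, T cell, monocyte, cytotoxic and both published lists, it takes 4 members of smallest p. Where fewer than 5 genes pass in a direction, it takes the 5 of smallest p. The text uses up to 6 and 3 of the first 2 kinds, those well above background on at least 1 array of each side; this shortening was set after the values were seen.

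Alternatives fixed in advance changed the background correction, the normalization, the channel, the source of values, the probe filter, the probe per gene, the variance model, array weights, scan day, the groups in the fit and the replicate numbers, and left out each array or pair. Alternatives added after seeing the data were scan day as a fixed term in every comparison, slide as a block, values within single scan days or runs, the value table with the 2 mismatched columns exchanged, the 2 scanner files exchanged instead, and the list tests in settings other than the estimated correlation. Others left out arrays of the older design, arrays with under 50% of probes well above background in Cy5, or arrays with a median absolute log2 ratio under 0.2. In a last one, 2 pairs of near-identical arrays (spread of the difference under 0.15, a limit set after the spreads were seen) were averaged, also within the shared scan run with scan day fixed, where the compressed array was left out in turn.

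The procedure was tested on simulated data. For a simulated log2 change of 1 it recovered 77.6% of changed genes for tolerance against chronic rejection, 56.7% and 40.3% for the comparisons of these groups with healthy controls, and 14.9% in the paired comparison. For a change of 2 it recovered 84.8% in the paired comparison. The simulated noise was normal and independent between genes and arrays, with each gene's own SD. It held no scan day effect, no likeness within patients and no near-identical or compressed arrays. Recovery on the real arrays can therefore differ from these percentages. The number of arrays limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.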

Results

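The 45 arrays covered kidney transplant recipients with stable function without immunosuppression (operational tolerance, 16 arrays), recipients with chronic rejection (10 arrays), healthy controls (5 arrays), and 7 patients of a tolerance induction protocol before and after transplantation. The series asks whether patients with induced tolerance show the expression signature of operational tolerance. Median Cy5 intensity per array ranged from 103 to 532, and 1.78 to 5.72 times the local background. Between 23.5% and 90.9% of probes were well above background in Cy5; the 5 healthy control arrays lay between 23.5% and 38.2% although their median intensity was 291 to 532. The median absolute log2 ratio was 0.24 to 0.70 on 42 arrays and lower on 3, namely chronic rejection replicates 7 (0.11) and 9 (0.19) and post-transplant replicate 7 (0.05), called compressed here. Scan days followed the groups closely: no healthy control array shared a day with tolerance or chronic rejection arrays, and post-transplant arrays shared none with tolerance arrays and 1 with chronic rejection arrays.

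Operational tolerance against chronic rejection compared recipients who keep a graft without drugs with those whose grafts are chronically rejected. Drug treatment was not part of the fit, so the contrast cannot separate graft outcome from it. Natural killer and cytotoxic lymphocyte transcripts had higher ratios in tolerance: the median log2 change of the list was 0.66, with 22 of 23 members above 0 (16 and 10 arrays). Within it KLRF1, an activating natural killer receptor, had a log2 change of 1.68 ± 0.51 and SH2D1B, a signalling adaptor of these cells, of 1.68 ± 0.57, while NCR1, another such receptor, differed 2.84-fold. Antibody-secreting cell transcripts were also higher, led by the immunoglobulin joining chain JCHAIN (log2 change 1.90 ± 0.38, 3.73-fold, above the chronic rejection mean on 16 of 16 arrays), IGHG1 (2.07 ± 0.45) and the plasma cell receptor TNFRSF17 (1.34 ± 0.40). No single gene passed in limma (0 of 26189, smallest adjusted p = 0.276), with 1807 genes at an unadjusted p under 0.05 and 1309 expected.

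At the preset correlation 10 of the 23 lists passed between tolerance and chronic rejection. Higher in tolerance were the cytotoxic list (adjusted p = 2.07e-07), plasma cell markers (median 0.31, adjusted p = 2.56e-05), cytosolic ribosomal proteins (median 0.34, adjusted p = 2.33e-11), heat shock genes (0.17, adjusted p = 0.00257), immediate early genes (0.31, adjusted p = 0.00177), dendritic cell markers (0.29, adjusted p = 0.0347), co-stimulation genes (0.21, adjusted p = 0.0347) and the published panel of 10 tolerance genes (0.49, adjusted p = 0.00257). Lower were erythroid markers (−0.69, adjusted p = 4.78e-05) and granulocyte markers (−0.19, adjusted p = 0.0168). Plasma cell markers and heat shock genes also passed with an estimated correlation (adjusted p = 0.0326 for each). The ribosomal list then had adjusted p = 0.172, the immediate early list adjusted p = 0.440, and the cytotoxic, dendritic, co-stimulation, erythroid, granulocyte and 10-gene lists adjusted p = 0.436 each. Adjusted over the list alone, 5 cytotoxic, 5 plasma cell, 14 ribosomal and 2 heat shock members passed, and 0 members of each list passed over all genes. The 13 other lists had adjusted p from 0.0571 to 0.978, among them B cell markers (median 0.27, adjusted p = 0.0581). Some calls ended with 1 array left out. Immediate early genes did not pass without tolerance replicate 2 (0.16, adjusted p = 0.0922). The 10-gene panel did not pass without chronic rejection replicate 7 (0.33, adjusted p = 0.0502). Granulocyte markers did not pass without chronic rejection replicate 4 (−0.11, adjusted p = 0.0626) or tolerance replicate 8 (−0.10, adjusted p = 0.0543). The call of dendritic cell markers ended without any 1 of chronic rejection replicates 7, 9 and 10 and tolerance replicates 8, 10, 11 and 16 (0.17 to 0.29, adjusted p 0.0522 to 0.157). The call of co-stimulation genes ended without any 1 of chronic rejection replicates 5, 7 and 9 and tolerance replicates 1, 8, 10 and 11 (0.14 to 0.22, adjusted p 0.0507 to 0.153). Medians that moved by over 1.5 times while the list still passed were the cytotoxic one without chronic rejection replicate 7 (0.41), the erythroid one without tolerance replicate 2 (−0.46) and the granulocyte one without chronic rejection replicates 2, 6, 7 or 9 or tolerance replicate 2 (−0.31 to −0.08).

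Of the other members, the globin HBD had a log2 change of −1.05 ± 0.54 and the granule protein LTF of −1.02 ± 0.50, both over 16 and 10 arrays. The chaperones HSPD1 and HSPE1 had 0.58 ± 0.19 and 0.53 ± 0.17, and the early activation marker CD69 had 1.28 ± 0.59. Of the 3 genes of the published assay, CYP1B1, a xenobiotic-metabolizing enzyme, had 1.09 ± 0.35, while BNC2 was well above background on 7 of 16 and 1 of 10 arrays, so its change cannot be read, and KLF6 had 0.05 ± 0.27 (list adjusted p = 0.0571). The B cell genes TCL1A and PNOC had 1.21 ± 0.61 and 0.66 ± 0.31, and the T cell gene TCF7 had −0.47 ± 0.30. Genes of smallest p with lower ratios in tolerance were CERCAM (−1.17 ± 0.27), DRP2 (−1.04 ± 0.24) and MAGEA8 (−1.69 ± 0.42), each with adjusted p above 0.3. CERCAM was well above background on 6 of 16 and 8 of 10 arrays, so the size of its change is uncertain.

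Scan day changed some of these results. Fitting scan day as a fixed term gave 14 genes, and the cytotoxic list had a median of 1.35 (1.47 within day E, 3 and 3 arrays, and 1.23 within day G, 5 and 2 arrays). Day G holds both pairs of near-identical arrays, so whether its 2 chronic rejection arrays are distinct samples is not settled. With these pairs averaged the cytotoxic median within the shared scan run was 1.29, and without the compressed array it was 1.04. The plasma cell list had 0.29 (0.52 and 0.13 within these days), the erythroid list −0.61 (−0.14 and −0.95), the granulocyte list −0.43 (0.02, where the test pointed lower, and −0.65) and the 10-gene panel 1.21 (1.42 and 1.04). Immediate early genes no longer passed (0.11, adjusted p = 0.580), nor did co-stimulation genes (0.01, adjusted p = 0.0968). Without the compressed arrays 24 genes passed, JCHAIN among them, and the cytotoxic median was 0.41. Without arrays of under 50% well above background that median was 0.33. Array weights in limma gave 1310 genes, 852 higher and 458 lower.

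Operational tolerance against healthy controls placed the tolerant recipients beside people without a transplant. Inflammatory genes were far lower in tolerance: the chemokine CXCL2 fell by 6.23 ± 0.81 on the log2 scale (16 and 5 arrays). It was well above background on 8 and 4 of these, so the size of its change is uncertain. The cytokine IL1B fell by 5.19 ± 0.78 and NFKBIA, the inhibitor of NF-kB, fell by 4.32 ± 0.46. Immediate early genes, which cells switch on within minutes of a stimulus, fell with them, as CD69 (−4.77 ± 0.75), JUN (−3.33 ± 0.53) and the phosphatase DUSP2 (−2.64 ± 0.32). Not all patient groups were low in immediate early genes. The list averaged 0.75 in tolerance and 2.81 in healthy controls, but 2.67 before and 2.59 after transplantation. Among the genes of largest rise in tolerance were CXCR1, the neutrophil receptor of CXCL8 (3.83 ± 0.41), CCR2, the monocyte chemokine receptor (3.62 ± 0.47), and P2RY13 (3.78 ± 0.64). These 3 were well above background on 16 tolerance arrays but on 1, 2 and 1 of 5 healthy control arrays, so the size of these changes is uncertain.

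In limma 6763 of 26189 genes differed between tolerance and healthy controls, 4014 higher and 2749 lower. NF-kB targets had a median of −2.50 (17 of 26 lower, 19 adjusted over the list alone, adjusted p = 3.77e-16) and immediate early genes −1.93 (23 of 27 lower, 24 adjusted over the list alone, adjusted p = 1.01e-15). Calcineurin and NFAT targets had −0.66 (6 of 14 lower, 7 adjusted over the list alone, adjusted p = 0.00131), with TNF, also in the NF-kB list, at −3.23 ± 0.52. These had adjusted p = 0.0973 each with an estimated correlation. Monocyte markers had a median of 1.18 (8 of 22 higher, 12 adjusted over the list alone, adjusted p = 0.00106), such as MNDA, a myeloid nuclear protein (2.57 ± 0.44), and CSF1R, the receptor of macrophage growth factor (2.34 ± 0.53). Granulocyte markers had a mean of 1.11 (9 higher and 1 lower of 19, 10 and 1 adjusted over the list alone, adjusted p = 0.00295). Interferon response genes had −0.61 (3 of 26 lower, also 3 adjusted over the list alone, adjusted p = 0.0184) and ribosomal proteins −0.27 (2 higher and 6 lower of 56, 2 and 5 adjusted over the list alone, adjusted p = 0.00414). With an estimated correlation the granulocyte list had adjusted p = 0.491 and the monocyte, interferon and ribosomal lists adjusted p = 0.920. Without healthy control replicate 4 monocyte markers did not pass (0.61, adjusted p = 0.226). Interferon genes did not pass without replicate 1 (0.12, where the test pointed lower, adjusted p = 0.860) or replicate 2 (−0.23, adjusted p = 0.0691). The interferon median was −0.94 and −0.93 without replicates 3 and 4, and the granulocyte median fell by over 1.5 times to 0.71 (adjusted p = 0.0318) without replicate 5. The other 16 lists had adjusted p from 0.177 to 0.981; TCL1A and CYP1B1 rose by 2.55 ± 0.77 and 2.48 ± 0.45 (CYP1B1 well above background on 2 of 5 control arrays, so its size is uncertain), and CX3CR1 by 2.81 ± 0.73.

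No scan day held both tolerance and healthy control arrays, so no within-day value exists. With scan day as a fixed term in the fit of 4 groups, which ties the groups through few arrays, 1100 genes passed, NF-kB targets had a median of −5.53 and granulocyte markers of −0.07, with the test pointing the other way (adjusted p = 0.417). A random block for scan day gave 1659 genes. The balance of directions moved with the scaling. The software's log ratio shifted the median of all genes from 0.08 to 0.36 and gave 6415 higher and 1516 lower, the authors' value table to 0.42 with 7033 and 1227, and median centring gave 3573 and 3693.

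Chronic rejection against healthy controls asked the same of recipients whose grafts are chronically rejected. Again inflammatory genes were lower than in the controls: G0S2, an inhibitor of lipolysis induced in activated leukocytes, fell by 6.75 ± 0.84 (10 and 5 arrays). CXCL2 fell (well above background on 4 of 10 and 4 of 5, so its size is uncertain), CCL3 fell by 5.99 ± 0.60 and CD69 fell by 6.04 ± 0.81. Pre- and post-transplant arrays did not share this low level: immediate early genes averaged 2.67 and 2.59 there, against 0.40 in chronic rejection and 2.81 in controls. Cytotoxic genes fell too, as GZMB, a killer cell protease (−2.20 ± 0.55), FGFBP2 (−2.54 ± 0.73) and the receptor KLRB1 (−2.93 ± 0.93), each lower on 10 of 10 arrays, although scale normalization between arrays turned them to 1.09, 0.53 and 0.25 (adjusted p of 0.836 or more). CXCR1 rose by 4.01 ± 0.44 and the erythroid genes TRIM58 and SELENBP1 by 3.31 ± 1.06 and 2.65 ± 0.74. These were well above background on 1, 2 and 5 of 5 healthy control arrays, so the size of the first 2 changes is uncertain.

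In this comparison 6928 genes differed in limma, 3955 higher and 2973 lower in chronic rejection. NF-kB targets had a median of −2.50 (17 of 26 lower, 21 adjusted over the list alone, adjusted p = 5.77e-17), immediate early genes −2.24 (24 of 27, 25 adjusted over the list alone, adjusted p = 1.01e-17) and calcineurin and NFAT targets −0.91 (7 of 14, also 7 adjusted over the list alone, adjusted p = 0.000254). They had adjusted p = 0.0878, 0.0878 and 0.0624 with an estimated correlation. Ribosomal proteins had −0.53 (24 of 56 lower, 2 higher and 27 lower adjusted over the list alone, adjusted p = 2.69e-07), as RPS29 (−1.75 ± 0.29). Cytotoxic markers had −1.33 (4 of 23 lower, 3 adjusted over the list alone, adjusted p = 0.00723) and interferon genes −0.74 (2 of 26 lower, also 2 adjusted over the list alone, adjusted p = 0.0188), as IFI44 (−2.21 ± 0.59). Granulocyte markers had 1.44 (10 of 19 higher, 11 adjusted over the list alone, adjusted p = 0.000164), erythroid markers 1.26 (6 of 18 higher, 11 adjusted over the list alone, adjusted p = 0.00329) and monocyte markers 0.88 (7 higher and 1 lower of 22, 9 and 1 adjusted over the list alone, adjusted p = 0.0108). With an estimated correlation the adjusted p was 0.336 for ribosomal proteins, 0.873 for cytotoxic and interferon genes, 0.212 for granulocyte markers and 0.851 for erythroid and monocyte markers. Some calls ended with 1 healthy control array left out. They were monocyte markers (replicate 4: 0.02, adjusted p = 0.618) and interferon genes (replicate 1: 0.04, where the test pointed lower, adjusted p = 0.867; replicate 2: −0.52, adjusted p = 0.0576). They were also cytotoxic markers (replicate 3: −0.82, adjusted p = 0.102; replicate 5: −1.07, adjusted p = 0.0508) and erythroid markers (replicate 5: 1.17, adjusted p = 0.0669). The calcineurin and NFAT median was −0.56 without replicate 1, and the interferon median −1.17 and −1.13 without replicates 3 and 4, all still past the test. The other 14 lists had adjusted p from 0.0586 to 0.921.

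No scan day held both chronic rejection and healthy control arrays. With scan day as a fixed term in the fit of 4 groups, 1205 genes passed, the cytotoxic median turned to 0.71 (adjusted p = 0.421) and the granulocyte median was 0.42 (adjusted p = 0.111), while scan day as a random block gave 1724 genes. The software's log ratio moved the median of all genes from 0.07 to 0.26 with 5395 higher and 2190 lower, the authors' table to 0.34 with 5961 and 1798, and median centring gave 2683 and 4066. Without the compressed arrays the cytotoxic (−0.73) and interferon (−0.62) lists no longer passed (adjusted p = 0.0571 each); the first median shrank by over 1.5 times and the second stayed within that. The erythroid median in the Cy3 channel alone was 0.65, which would lower the ratio.

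**Figure D1:**
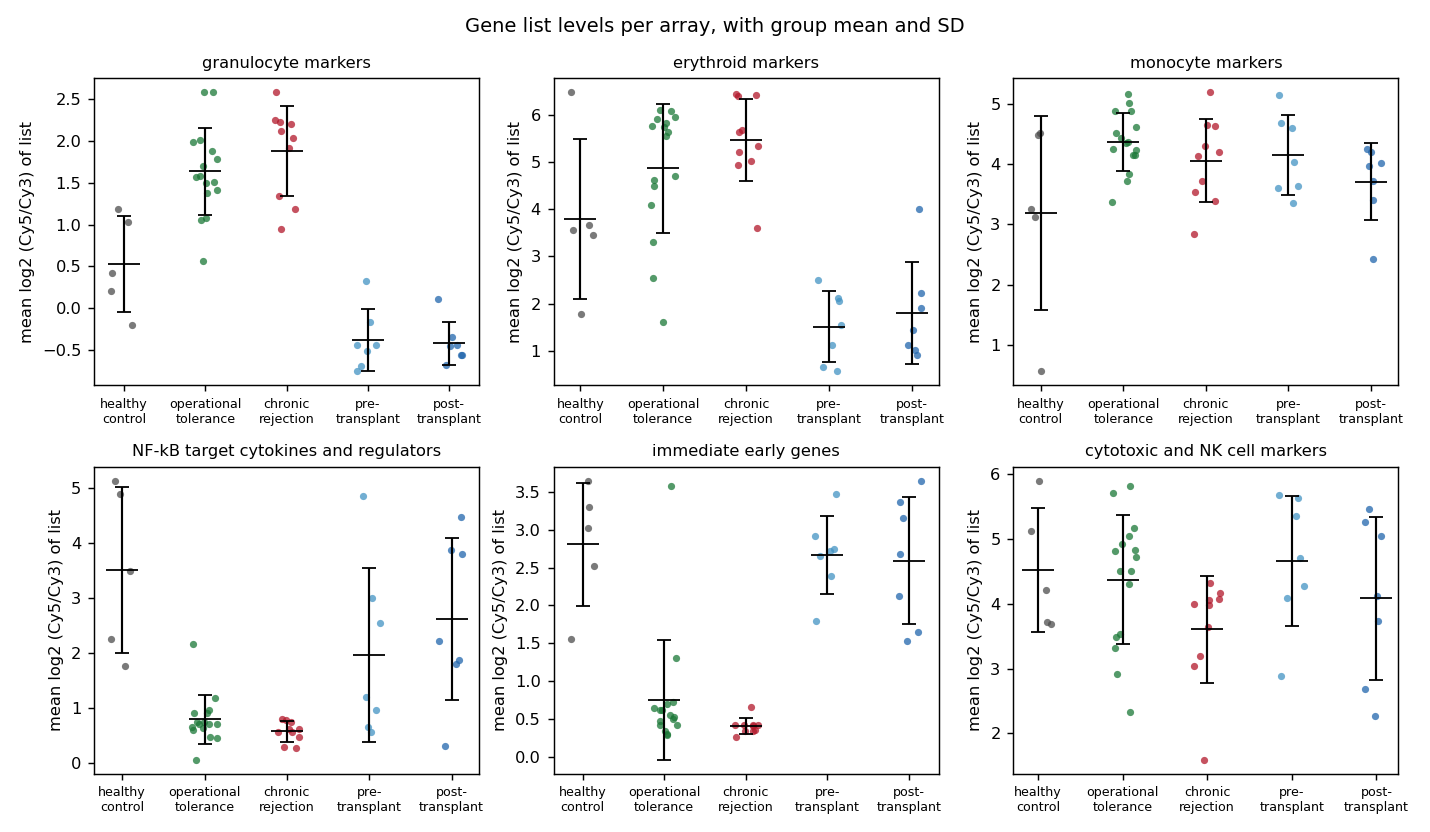
Mean log2 ratio of Cy5 over Cy3 for 6 gene lists (vertical axes) on each array, by group (horizontal axes); points are arrays, and bars show the mean and SD of the group. Granulocyte markers averaged 1.63 in tolerance and 1.88 in chronic rejection, against −0.38 before and −0.42 after transplantation.

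Post-transplant patients against operational tolerance set patients of the induction protocol beside recipients with spontaneous tolerance. No scan day held both groups, and some leading differences were already there before transplantation. The contrast therefore cannot by itself compare induced with spontaneous tolerance. Red cell and granulocyte genes were much lower after transplantation: the globins HBQ1 and HBM fell by 6.05 ± 0.88 and 5.81 ± 0.86 (7 and 16 arrays), CXCR1 fell by 4.56 ± 0.36, its relative CXCR2 fell by 4.41 ± 0.36 and CLC, an eosinophil and basophil protein, fell by 4.05 ± 0.45. Inflammatory and early activation genes were higher, as CXCL2 (5.45 ± 0.72), IL6 (4.69 ± 0.82), ATF3, a stress-induced transcription factor (4.20 ± 0.62), and CD69 (4.10 ± 0.67). CXCL2 was well above background on 7 and 8 arrays, so the size of its change is uncertain. Among T cell genes the interleukin-7 receptor IL7R fell by 3.74 ± 0.45 and CD27 fell by 2.97 ± 0.53, each below the tolerance mean on 7 of 7 arrays. Granulocyte, erythroid and immediate early lists had similar levels before transplantation. Granulocyte markers averaged −0.38 ± 0.37 (SD, n = 7) before and −0.42 ± 0.26 after, against 1.63 ± 0.52 in tolerance. Erythroid markers averaged 1.51 ± 0.75 and 1.81 ± 1.08 against 4.87 ± 1.36, and immediate early genes 2.67 ± 0.51 and 2.59 ± 0.84 against 0.75 ± 0.79. The T cell and NF-kB lists were less alike. T cell markers averaged 2.24 ± 0.86 before and 1.81 ± 0.99 after, against 2.68 ± 0.57 in tolerance. NF-kB targets averaged 1.97 ± 1.58 and 2.62 ± 1.48 against 0.79 ± 0.44.

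Here 6214 genes differed in limma, 2288 higher and 3926 lower after transplantation. Erythroid markers had a median of −3.06 (15 of 18 lower, 16 adjusted over the list alone, adjusted p = 1.33e-11), granulocyte markers −2.00 (13 of 19, 1 higher and 14 lower adjusted over the list alone, adjusted p = 2.60e-09) and T cell markers −0.84 (6 of 20, 10 adjusted over the list alone, adjusted p = 0.0299). Immediate early genes had 1.98 (20 of 27 higher, 23 adjusted over the list alone, adjusted p = 6.36e-15), NF-kB targets 1.38 (16 of 26, 17 adjusted over the list alone, adjusted p = 9.58e-11) and MHC class II genes 0.67 (5 of 13, 6 adjusted over the list alone, adjusted p = 0.0352), as CD74, the invariant chain (1.39 ± 0.38). With an estimated correlation the adjusted p was 0.246 for erythroid, 0.0619 for granulocyte, 0.943 for T cell, 0.158 for immediate early, 0.253 for NF-kB and 0.901 for MHC class II genes. T cell markers did not pass without any 1 of tolerance replicates 8 and 15 and post-transplant replicates 5, 6 and 7 (−0.77 to −0.59, adjusted p 0.0543 to 0.194). MHC class II genes did not pass without any 1 of tolerance replicate 9 and post-transplant replicates 1, 4 and 8 (0.55 to 0.65, adjusted p 0.0525 to 0.0932). The other 17 lists had adjusted p from 0.0549 to 0.910. MNDA, FCGR3A, an Fc receptor of natural killer cells and monocytes, and CX3CR1 fell by 3.44 ± 0.39, 2.33 ± 0.37 and 2.89 ± 0.65, with FCGR3A at 1.19 (adjusted p = 0.787) under scale normalization.

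No scan day held both post-transplant and tolerance arrays. With scan day as a fixed term in the fit of 4 groups 1052 genes passed, with list medians of −1.51 for granulocyte, −2.69 for erythroid, 2.03 for immediate early and 4.21 for NF-kB genes, while T cell (−0.20, adjusted p = 0.452) and MHC class II genes (−0.17, adjusted p = 0.664) no longer passed. Without the compressed arrays T cell markers had −0.77 (adjusted p = 0.0739). The share of higher genes moved from 36.8% to 49.7% with the Cy5 channel alone (2870 higher and 2905 lower) and to 47.7% with median centring (2382 and 2609). The Cy3 reference channel alone gave 1313 genes between these groups. Its erythroid median was −0.65, which would raise the ratio rather than lower it.

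Post-transplant patients against chronic rejection set the induced tolerance patients beside recipients whose grafts are chronically rejected. Globins fell again, as HBM (−6.59 ± 0.94) and HBD (−5.41 ± 0.66, 7 and 10 arrays), and so did the granulocyte receptors CXCR1 (−4.75 ± 0.39) and CXCR2 (−4.46 ± 0.39). Early activation genes rose, as G0S2 (5.95 ± 0.76), CD69 (5.38 ± 0.73), ATF3 (4.28 ± 0.67) and the chemokine CCL3 (4.68 ± 0.54). The plasma cell genes JCHAIN and PRDM1, the latter a master regulator of antibody-secreting cells, rose by 2.33 ± 0.47 and 1.58 ± 0.40, and LRRC32, a surface protein of activated regulatory T cells, by 2.00 ± 0.50.

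In limma 6427 genes differed, 2617 higher and 3810 lower after transplantation than in chronic rejection. Granulocyte markers had a median of −2.34 (15 of 19 lower, 16 adjusted over the list alone, adjusted p = 4.20e-11) and also passed with an estimated correlation (adjusted p = 0.0259). Erythroid markers had −3.90 (16 of 18, 17 adjusted over the list alone, adjusted p = 1.98e-14), T cell markers −0.71 (6 of 20, also 6 adjusted over the list alone, adjusted p = 0.0128), immediate early genes 2.23 (22 of 27, 23 adjusted over the list alone, adjusted p = 4.53e-17) and NF-kB targets 1.42 (14 of 26, 17 adjusted over the list alone, adjusted p = 2.18e-11). Plasma cell markers had 0.40 (3 of 12, also 3 adjusted over the list alone, adjusted p = 0.0393), regulatory T cell markers 0.28 (3 of 11, also 3 adjusted over the list alone, adjusted p = 0.0393), calcineurin and NFAT targets 0.44 (5 of 14, also 5 adjusted over the list alone, adjusted p = 0.0201), MHC class II genes 0.54 (6 of 13, also 6 adjusted over the list alone, adjusted p = 0.0393) and ribosomal proteins 0.30 (19 of 56, 21 adjusted over the list alone, adjusted p = 0.000600). With an estimated correlation the adjusted p was 0.132 for erythroid, 0.736 for T cell and MHC class II, 0.101 for immediate early, 0.175 for NF-kB and calcineurin, 0.355 for plasma cell and regulatory T cell, and 0.598 for ribosomal genes. With 1 array left out T cell markers did not pass without post-transplant replicate 6 (−0.43, adjusted p = 0.0874). Plasma cell markers did not pass without chronic rejection replicates 5, 7 or 9 or post-transplant replicates 1, 4 or 7 (0.22 to 0.44, adjusted p 0.0539 to 0.143). Regulatory T cell markers did not pass without chronic rejection replicates 1, 7 or 9 or post-transplant replicates 1 or 2 (0.21 to 0.29, adjusted p 0.0523 to 0.0655). The MHC class II call ended without chronic rejection replicates 5, 7, 9 or 10 or post-transplant replicates 1, 2, 4 or 8 (0.46 to 0.57, adjusted p 0.0507 to 0.126). The plasma cell median was 0.61 and 0.73 without post-transplant replicates 2 and 6, and the regulatory T cell median 0.13 without replicate 5, all still past the test. The other 13 lists had adjusted p from 0.136 to 0.944.

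Scan day D alone held both groups, with 1 post-transplant and 5 chronic rejection arrays, and 2568 genes passed within it; the single array is assumed to vary like the others. Scan day as a fixed term, which rests on the same array, gave 1967 genes and, as within day D, list medians of −1.72 for granulocyte, −3.82 for erythroid, 1.98 for immediate early and 4.03 for NF-kB genes. T cell (−0.28, adjusted p = 0.633), MHC class II (0.31, adjusted p = 0.588) and plasma cell markers (−0.39, adjusted p = 0.824) no longer passed. Without the compressed arrays plasma cell genes (0.17, adjusted p = 0.249) and MHC class II genes (0.59, adjusted p = 0.0517) did not pass either, though the second median did not shrink. The software's log ratio moved the median of all genes from −0.00 to 0.12, with 4081 higher and 3745 lower, median centring gave 3059 and 2263, and the Cy3 channel alone gave 3688 genes. The erythroid median in Cy3 was −1.04, which would raise the ratio.

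Post-transplant against pre-transplant samples of the same 7 patients asked what the protocol and the transplant changed. B cell transcripts had higher ratios after transplantation, with all 25 list members above 0 and a median log2 change of 0.75 (0.44 without pair 4): PNOC, a neuropeptide precursor made by B cells, had 1.53 ± 0.39, HLA-DOB 0.70 ± 0.20 and the B cell receptor component CD79A 0.98 ± 0.36, each higher in 6 of 7 pairs (5 of 7 with the 2 mismatched scanner files exchanged). Among the genes of smallest p, none of which passed, GIMAP6 had −1.28 ± 0.16, GIMAP8 −2.13 ± 0.38 and GIMAP4 −1.23 ± 0.26, each lower in 7 of 7 pairs. The heat shock gene HSPA6 had −1.44 ± 0.28 and the interferon-induced helicase DDX60 −0.75 ± 0.16, also in 7 of 7 pairs, and IL7R had −1.66 ± 0.52. The 7 of 7 tallies were the same with those files exchanged. No gene passed in limma (0 of 26189, smallest adjusted p = 0.558 for GIMAP6), with 863 at an unadjusted p under 0.05 and 1309 expected.

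Of the lists, 9 passed in the paired comparison at the preset correlation and none with an estimated one, where the adjusted p was 0.644 for B cell and heat shock genes and 0.783 for the other 7. At the preset correlation B cell (adjusted p = 1.88e-15), plasma cell (median 0.46, adjusted p = 0.00158), NF-kB (0.61, adjusted p = 0.000558) and cell cycle genes (0.23, adjusted p = 0.000217) were higher. T cell (−0.30, adjusted p = 0.000328), cytotoxic (−0.56, adjusted p = 0.00158), monocyte (−0.36, adjusted p = 0.00123), heat shock (−0.21, adjusted p = 0.00379) and ribosomal genes (−0.10, adjusted p = 0.000197) were lower. Without pair 7, whose post-transplant array had compressed ratios, 1 of the 9 passed, the B cell list (median 0.70, adjusted p = 7.56e-09). The NF-kB (0.54, adjusted p = 0.0501), T cell (−0.27, adjusted p = 0.0651), heat shock (−0.14, adjusted p = 0.0651) and monocyte (−0.26, adjusted p = 0.137) medians then stayed within 1.5 times. The plasma cell (0.21, adjusted p = 0.175), cell cycle (0.09, adjusted p = 0.177) and ribosomal (−0.05, adjusted p = 0.139) medians shrank further. The cytotoxic median was 0.03, where the test pointed lower (adjusted p = 0.887). NF-kB genes did not pass without pair 2 (0.10, adjusted p = 0.240) or 8 (0.25, adjusted p = 0.0597) either. Monocyte markers did not pass without pair 4 (−0.17, adjusted p = 0.413), nor heat shock genes without pair 5 (−0.12, adjusted p = 0.0905). Still past the test, medians moved by over 1.5 times without pair 4 to 0.44 for B cell, 1.13 for NF-kB, −0.62 for T cell, −0.84 for cytotoxic, −0.32 for heat shock and −0.15 for ribosomal genes. Without pair 5 they moved to 1.14 for NF-kB, 0.37 for cell cycle and −0.62 for monocyte genes. Adjusted over the list alone, 1 heat shock member and 0 members of the others passed, and over all genes 0 passed. An exact sign-flip test of the mean of each list over the 7 pairs gave adjusted p of 0.359 or more, with B cell markers at 0.81 ± 1.12 (SD, 5 of 7 pairs higher, exact p = 0.109; 4 of 7 and 0.172 with the files exchanged). With scan day as a fixed term the B cell median was 0.79, plasma cell 0.53, NF-kB 1.14, cell cycle 0.37, T cell −0.29, cytotoxic −0.46, monocyte −0.62, ribosomal −0.10 and heat shock −0.12, the last no longer past the test (adjusted p = 0.0911). Only pair 5 had its arrays scanned on different days (H before and J after transplantation). With the patient as a block, fitting scan day therefore amounts to leaving out pair 5 and is no separate check. The other 14 lists had adjusted p from 0.0589 to 0.976, including the published panel (median 0.78, adjusted p = 0.129).

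**Figure D2:**
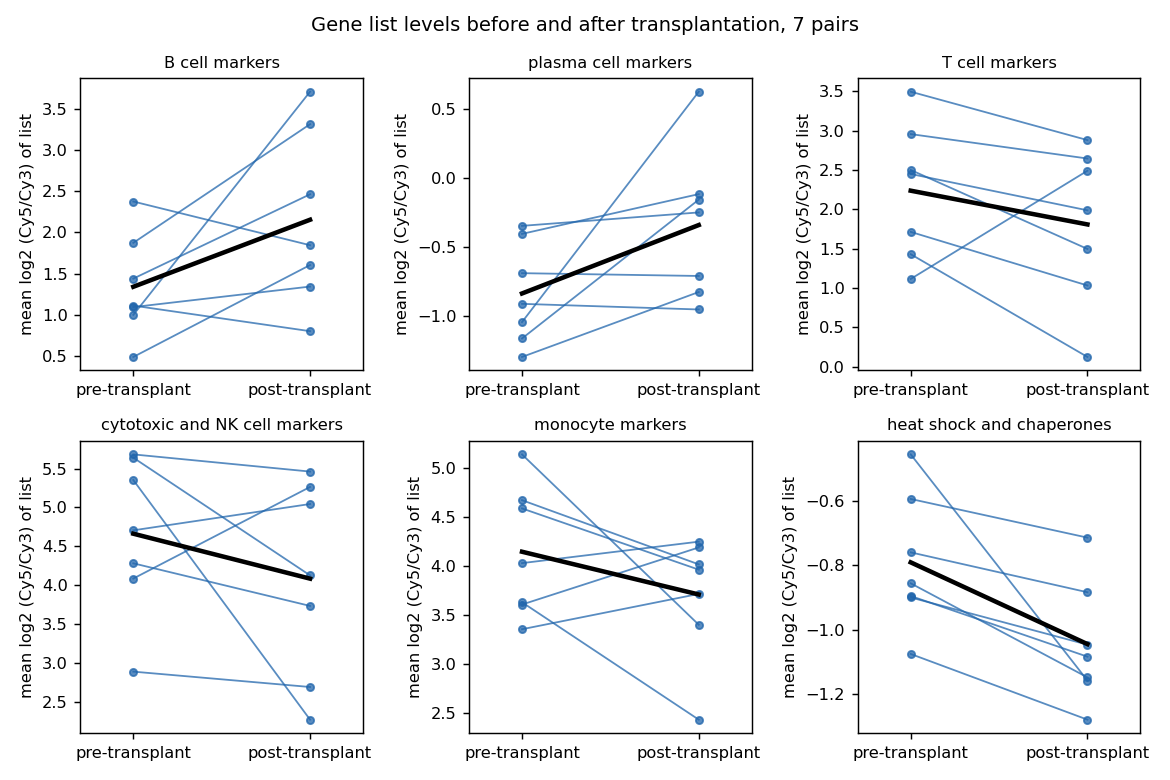
Mean log2 ratio of Cy5 over Cy3 for 6 gene lists (vertical axes) before and after transplantation (horizontal axes); thin lines join the arrays of each of 7 patients and the black line joins the means. B cell markers averaged 1.34 before and 2.15 after, and heat shock genes were lower after transplantation in 7 of 7 pairs.

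The signature score asked whether the induced tolerance patients moved toward operational tolerance. It rested on 50 genes higher and 50 lower in tolerance than in chronic rejection, none of which passed (highest adjusted p = 0.426). The mean score was −0.06 ± 0.29 (SD, n = 7) before and −0.16 ± 0.40 after transplantation, −0.05 ± 0.46 in 5 healthy controls, −0.13 ± 0.50 in tolerance and −1.74 ± 0.71 in chronic rejection; the genes were picked on the last 2 groups, so their difference is not a test. The paired change was −0.10 ± 0.18 (SD), higher in 4 of 7 pairs, with an exact two-sided sign-flip p of 0.312, on the scanner files as labelled. The smallest p this design allows is 0.0156. Among the pairs counted as higher, pair 5 (−0.0980 to −0.0955) and pair 7 (−0.1697 to −0.1695) barely moved. The post-transplant array of pair 7 had compressed ratios. Across 25748 genes the post-minus-pre changes and the tolerance-minus-rejection changes had Pearson r = −0.137 and Spearman rho = −0.169 (exact sign-flip p = 0.0781); genes are not independent replicates, and sign patterns gave r from −0.195 to 0.195. Without pair 1 r was −0.172 with exact p = 0.0312, and without the compressed arrays it was −0.0452 with exact p = 0.250.

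**Figure D3:**
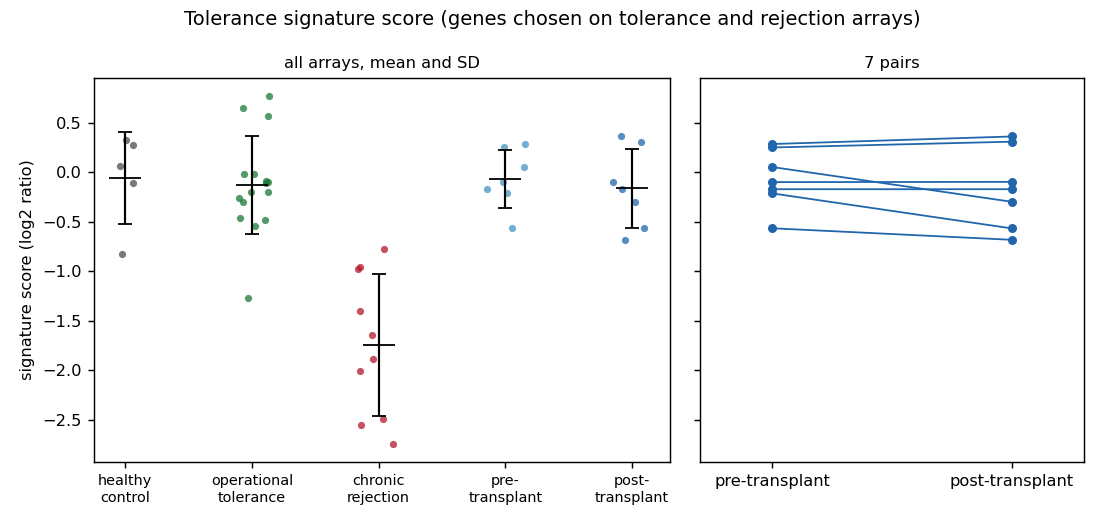
Signature score (log2 ratio units, vertical axes) for each array by group, with the mean and SD of the group, and before and after transplantation for each of 7 patients. The score averaged −0.06 before and −0.16 after transplantation, near −0.13 in tolerance and above −1.74 in chronic rejection, whose arrays with those of tolerance chose the genes.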

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

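The tests of the 3 patterns weighed here were chosen after the result was seen, except the test of arrays with few probes well above background, whose bounds were written before; that it needs a scan day with both kinds of array was added after.

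In 41 of 386 groups of 4 to 10 arrays, 1 array lay far from the others, where chance gives about 19; the values are the gap to the nearest array as a share of the whole range. Each gene and list was tested separately, so the outlying array can differ between items of a group. In chronic rejection an array lay lowest for BTG2 (0.517), CD79A (0.478), EFNB3 (0.507), FCN1 (0.799), GZMB (0.508), HBM (0.572), IKZF4 (0.492), LCN2 (0.547) and TNF (0.534), and for the list means of cytotoxic (0.531), erythroid (0.472) and TGF-beta pathway genes (0.469). An array lay highest there for CCL3 (0.644), CCL3L3 (0.784), CLEC4C (0.647), JCHAIN (0.468) and NFKBIA (0.582), and for the means of immediate early (0.596), glucocorticoid response (0.556) and cell cycle genes (0.472). Among post-transplant arrays 1 lay lowest for CD74 (0.670). A post-transplant array lay highest for CMTM2 (0.730), CYP1B1 (0.584), EFNB3 (0.597), GABRP (0.638), HBM (0.703), HBQ1 (0.751) and NR4A1 (0.655), and for the means of granulocyte (0.581), platelet (0.606), erythroid (0.573) and cell cycle genes (0.605). Before transplantation 1 array lay highest for the means of interferon response (0.576) and calcineurin and NFAT target genes (0.594). In healthy controls an array lay highest for DCAF10 (0.828), KCNQ3 (0.839), PGF (0.784), SELENBP1 (0.749) and TLR5 (0.725). An array lay lowest for MNDA (0.831) and for the mean of MHC class II genes (0.720).

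Granulocyte markers were lower after transplantation than in tolerance and chronic rejection at the preset correlation. With an estimated one the list passed against chronic rejection but not against tolerance. The reference channel is argued against as the source, since Cy3 alone changed by −0.0436 (median log2) between post-transplant and chronic rejection arrays, and so is the transplantation, since the mean paired change was −0.0356 ± 0.448 (SD, 7 pairs, exact p = 0.953). With scan day as a fixed term the median was −1.72, but 1 post-transplant array carries that value, so scan day and group cannot be told apart for the other arrays. A candidate explanation is RNA of mature granulocytes in the tolerance and chronic rejection samples, which a Ficoll gradient would mostly remove: 6 of 6 abundant transcripts of these cells were lower by at least 1, from ALPL (−2.16 ± 0.50) to CXCR1 (−4.75 ± 0.39), though these 6 come from the list that showed the pattern. A difference in collection or handling between the study arms and a biological difference in circulating granulocytes both stay open and untested.

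Immediate early and NF-kB target genes were higher in healthy controls than in tolerance at the preset correlation. Neither list passed with an estimated one. A larger share of monocytes in the controls would raise monocyte markers there, but these had a median of 1.18 in the other direction. Without healthy control replicate 4 the median was 0.61 and the list no longer passed camera (adjusted p = 0.226). The markers thus gave no sign of a larger share, but cells were not counted and RNA per cell can differ. All 5 control arrays had few probes well above background. In the scan run of both patient groups, 6 arrays with under 50% differed from 8 others by 0.13, against 2.38 between controls and tolerance. The 6 were all scanned on day E and the 8 on days F and G, so scan day may hide an effect. Only 1 of 7 pre-transplant and 1 of 7 post-transplant arrays had under 50%. Immediate early genes still averaged at least 1.79 and 1.53 on each array of these groups. A high level thus did not need few probes well above background, but its part in the controls cannot be told apart from the group. The reference channel changed by 0.15 in the NF-kB list. Against tolerance, scan day and sample handling follow the control group and cannot be told apart from it. Immediate early genes were also high on pre- and post-transplant arrays, 2.67 ± 0.51 and 2.59 ± 0.84 (SD, n = 7 each), over days C, D, H, I and J. They averaged 2.81 ± 0.81 in controls and 0.75 ± 0.79 in tolerance. For this list, these values argue against a difference between healthy people and all recipients. NF-kB targets were too spread to say (1.97 ± 1.58 and 2.62 ± 1.48, beside 3.50 ± 1.51 in controls). Other biological differences between controls and tolerance stay open.

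Cytotoxic and natural killer markers were higher in tolerance than in chronic rejection at the preset correlation, with an adjusted p of 0.436 under an estimated one. Dilution by erythroid and granulocyte RNA would lower T cell markers alike, but the cytotoxic change exceeded the T cell change by 0.79 (permutation p = 0.0184). That permutation ignored scan day and kept the 2 compressed chronic rejection arrays. It was not repeated without them, so compressed ratios may add to this excess. Within the scan run that holds both groups (9 and 5 arrays), with scan day as a fixed term, the median was 1.35. Camera gave adjusted p = 1.20e-23 there at the preset correlation, and an estimated correlation was not tried. The median was 1.29 with near-identical arrays averaged and 1.04 without the compressed array of that run. These changes were not combined in 1 fit. Fitting scan day did not shrink the median, which argues against scan day as its source. Compressed ratios on 2 chronic rejection arrays could account for part of it, since without them the median was 0.41 (adjusted p = 0.00898), as without replicate 7 alone (0.41). The list averaged 4.37 in tolerance and 3.61 in chronic rejection. It averaged 4.53 in healthy controls, 4.66 before and 4.09 after transplantation. Chronic rejection was thus the lowest group, and tolerance did not stand above healthy controls. Drug treatment was not part of these fits, so the change cannot be assigned to graft outcome. A different share of natural killer cells in the 2 patient groups remains a hypothesis, found and tested on the same arrays.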

How the results depend on the processing

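Chosen after seeing the data were scan day as a fixed term in the fit of 4 groups, slide as a block, values within scan days or runs, leaving out arrays with under 50% of probes well above background or with compressed ratios or of the older design, averaging near-identical arrays, exchanging 2 columns or 2 scanner files, and all list tests except those with an estimated correlation; the other alternatives here were planned. Signal of 1.78 to 5.72 times background limits what weak probes can show.

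Tolerance against chronic rejection gave 0 genes, and 1310 with array weights, 14 with scan day fixed, 2 with only those 2 groups fitted, 5 within the shared scan run, 7 there with scan day fixed and no compressed array, 40 within day G, whose 2 chronic rejection arrays are near-identical, and 24 without compressed arrays. Post-transplant against pre-transplant gave 0 genes in all 17 other settings. The strict probe filter, which tests fewer genes, gave 2346 and 2769 genes for tolerance and chronic rejection against healthy controls, and 4126 and 4123 for post-transplant against tolerance and chronic rejection. Against healthy controls, tolerance and chronic rejection gave 3575 and 3773 genes with scale normalization, 1659 and 1724 with scan day as a random block, 1100 and 1205 with it fixed in the fit of 4 groups, and 3969 and 3941 with slide as a block. Tolerance against healthy controls gave 4338 with Cy5 alone. Post-transplant against tolerance gave 3884 with scan day random and 1052 fixed, and against chronic rejection 1967 with scan day fixed and 2568 within day D, both resting on 1 post-transplant array, assumed to vary like the others. Scan day shares its variation with the groups; for the rest the cause was not tested.

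Replicate numbers pair no patients across groups, and as a block gave 4181 genes for tolerance against healthy controls and 2905 for post-transplant against tolerance. Among 10, 5, 5, 7 and 7 shared numbers in the 5 comparisons, 0, 2, 1, 1 and 2 samples resembled their own number best. Leaving out 1 array gave 0 to 0 genes for tolerance against chronic rejection, 4601 to 7150 and 4860 to 7112 for tolerance and chronic rejection against healthy controls, 4828 to 7339 and 5189 to 7228 for post-transplant against tolerance and chronic rejection, and 0 to 0 for the pairs.

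The score change ran from −0.146 to 0.0317 with 1 array or pair left out and from −0.161 to 0.426 in the other settings, none past the test. The correlation of changes ran from −0.190 to −0.0279 with 1 array or pair left out, and passed without pair 1 (−0.172, exact p = 0.0312), with median centring (−0.214, exact p = 0.0469) and without arrays under 50% (−0.0981, exact p = 0.0312); in the other settings it ran from −0.532 to −0.00288.

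With an estimated correlation 2, 0, 0, 0, 1 and 0 lists passed in the 6 comparisons. The lists past the test numbered 12 for post-transplant against tolerance with scan day fixed, 5 against chronic rejection without arrays under 50%, and 1 for the pairs without compressed arrays. With 1 array or pair left out they ran from 7 to 14 for tolerance against chronic rejection, 6 to 8 and 7 to 10 for these against healthy controls, 5 to 7 and 7 to 12 for post-transplant against them, and 1 (without pair 7) to 12 for the pairs. MHC class II genes in tolerance against chronic rejection, whose mean and test pointed lower beside a median of 0.03, turned to 0.47 with scan day fixed (also within the run), 0.52 within the run with scan day fixed and near-identical arrays averaged, 0.34 there without the compressed array, 0.45 within the run, 0.63 within day E and 0.23 within day G. Interferon genes there turned to −0.58 within day G and −0.27 without arrays under 50%, and co-stimulation genes to −0.0706 within day G. For post-transplant against chronic rejection, scan day fixed and day D gave B cell −0.97, plasma cell −0.39, 10-gene panel −0.89, EBF1 −0.49 and PNOC −0.83. Interferon genes in the pairs turned to 0.40 with scan day fixed and to 0.40 without pair 5. These are the same check, because only pair 5 had its arrays on different scan days. In the fit of 4 groups with scan day fixed, cytotoxic markers turned to 1.88 and 0.71 and platelet markers to −1.85 and −1.54 in tolerance and chronic rejection against healthy controls, FGFBP2 to 0.35 in the latter, and B cell markers, whose test had pointed higher beside a median of −0.05, to −2.00 and MHC class II genes to −0.17 in post-transplant against tolerance. Scale normalization turned GZMB to 1.09, FGFBP2 to 0.53 and KLRB1 to 0.25 in chronic rejection against healthy controls, and FCGR3A to 1.19 and HBD to 1.35 in post-transplant against tolerance; by its construction it enlarges arrays of small spread, whose median absolute ratio went down to 0.05.

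Of the named genes' values, 9308 kept direction and side of the threshold, 346 no longer passed, 120 newly passed and 10 reversed. For gene lists these counts were 3044, 171, 142 and 24. Counts by direction stayed within 1.5 times in 390 settings and moved further in 62.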

Other observations

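Of the tests here, the B cell against T cell contrast was chosen after the list medians were seen, and exchanging files, averaging arrays and leaving out the compressed pair after the data were seen, while the splits of the arrays were planned.

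Heat shock and chaperone genes averaged −0.79 ± 0.21 (SD, n = 7) before and −1.05 ± 0.19 after transplantation, −0.62 ± 0.12 in tolerance, −0.82 ± 0.17 in chronic rejection and −0.93 ± 0.20 in 5 healthy controls. The paired change was −0.25 ± 0.21, lower in 7 of 7 pairs with exact p = 0.0156, the smallest this design allows, and an adjusted p of 0.359 over 23 lists. With the 2 mismatched scanner files exchanged the tally and exact p were the same. MHC class II genes averaged 4.22 ± 0.42 before and 4.21 ± 0.50 after transplantation, against 3.75 ± 0.26 in tolerance, 3.78 ± 0.57 in chronic rejection and 3.22 ± 1.11 in healthy controls. Cell cycle genes lay near −2.4 in each patient group that was compared without pairing: −2.41 ± 0.26 in tolerance, −2.40 ± 0.33 in chronic rejection and −2.36 ± 0.48 after transplantation. Among lists that did not pass, median, mean and test differed in sign in 23 list results, such as the published 3-gene assay in tolerance against healthy controls (median −0.55, mean 0.43). Platelet markers varied widely within groups, from 0.58 to 4.74 after transplantation.

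B cell transcripts may gain on T cell transcripts within patients after transplantation. The B cell list changed by 1.24 ± 0.81 (SD) more than the T cell list, above 0 in 6 of 7 pairs, with exact p = 0.0312 for this single contrast. Without pair 7, whose post-transplant array had compressed ratios, the difference was above 0 in 5 of 6 pairs, with exact p = 0.0625, and the smallest p that 6 pairs allow is 0.0312. Its mean was then 1.097 ± 0.775 (SD), so compressed ratios did not make most of it. Exchanging the scanner files of the 2 mismatched arrays cannot move the mean over pairs; the SD was then 0.89, with exact p = 0.0312. The Cy3 reference alone changed by 0.14 in the B cell and 0.01 in the T cell list, which would lower the contrast. Other technical explanations were not tested.

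Other splits of the arrays were refitted in the same way. For tolerance against healthy controls the real split was the only 1 of 100 with as many genes (6763, highest other 3905). The same held for chronic rejection against healthy controls (6928, highest other 1158). It held too for post-transplant against tolerance (6214, highest other 1501) and against chronic rejection (6427, highest other 861). No other split reached these 4 counts, but 100 splits cannot show a probability below 1 in 100. The splits break up scan days, so a difference between days is not excluded. For tolerance against chronic rejection 100 of 100 splits gave as many genes as the real one (0, highest other 140), and for the pairs 64 of 64 assignments did (0, highest other 1); with a real count of 0 every split gives as many, so the splits say nothing about chance there. Why a split gave 140 genes beside a real count of 0 was not tested.

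The values deposited by the authors had 2 columns that matched the scanner file of another array better than their own; no value decides whether columns or files were exchanged. Of 217 pairs of arrays within a group, 2 differed by a spread of 0.117 and 0.118 (log2), 1 pair in tolerance and 1 in chronic rejection, against 0.212 or more for the others. Replicated probes differed between these arrays by more than spot noise (0.0922 against 0.0230 and 0.128 against 0.0252), but spot noise leaves out variation between arrays, so this does not settle whether they are repeat arrays of a sample, and the 16 and 10 arrays may exceed the distinct samples. With each of these pairs averaged, 0 genes passed for tolerance against chronic rejection, 6354 and 6282 for these against healthy controls, and 5833 and 5775 for post-transplant against them.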
